A study of Solanum phureja with 20 samples.

How the data were processed

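RNA was compared between 4 lines of one potato (Solanum phureja) ploidy series on 20 two-colour spotted arrays. Per the labels' protocols, the series was made by chromosome doubling of a monoploid with 12 chromosomes and holds the monoploid (1x), the diploid lines 2xR3 and 2xR5, and a tetraploid (4x). Leaf RNA came from growing leaflets of 6 plants of each line 20 days after planting, and root RNA from growing root tips 7 days after planting. Root RNA was amplified before labelling, per the labels' protocols. Plants grew under 15 h of light at 23.5 °C and 9 h of dark at 15.5 °C, at 50% relative humidity. Each array compared 1 line labelled with Cy3 against another labelled with Cy5.

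Leaf replicates 1 and 2 and root replicates 4 and 5 were each a closed loop of 4 arrays in which each end line met both diploids and every line carried each dye once. Leaf replicate 3 was made of dye-swapped pairs, 1 pair for 1x with 4x and 1 pair for 2xR3 with 2xR5. The submitters describe the replicates as biological, but no label ties a replicate number to particular plants, so p-values measure the spread between these RNA samples.

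The values are log2 ratios of the 2 channels of each spot, as deposited by the authors. The submitters' processing notes name limma, with the version, background correction and within-array method not given in the sources used here. Array medians lay within 0.014 of 0, so the deposited log2 ratios had been centred. All values (100%, within 0.001) equalled the log2 of a ratio rounded to 2 decimals. Why a spot has no value is not given in the sources used here, and no spot intensities were used here. Signal over background, dim spots and slides could therefore not be examined.

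The direction of the ratio is not stated in the labels. It was read as Cy5 over Cy3, which is likely because that is limma's convention for a log ratio. If the reverse held, every sign below would turn and every size and p would stay. The relative orientation of the arrays could be tested. The labelled orientation left the smallest residual of all 2048 sign patterns of the leaf arrays and of all 128 of the root arrays. It left 34.7% of the leaf sum of squares, against 36.8% for the next best pattern, and 13.7% against 14.1% in root. The dye-swapped arrays of leaf replicate 3 correlated negatively across clones, with r = -0.585 for 1x with 4x and r = -0.511 for 2xR3 with 2xR5.

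The table holds 32448 spots. Read as duplicate spots of a clone, the print layout gave 15360 pairs. The pairing was inferred from the layout, with offsets taken from accessions that have 2 annotated spots. All 905 such accessions fell on a pair, which is therefore no separate test of the pairing. The 1728 spots outside the pairs held no value on any array. The 2 spots of a clone correlated at 0.517 to 0.952 over the arrays, against a mean of -0.005 for randomly paired spots. A clone's value was the mean of its spots with a value. In leaf 6001 clones had a value on every array, in root 8245, and 5121 in both.

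Names came from the platform annotation, which can be old and gives symbols without descriptions. It gave exactly 1 symbol for 1630 spots, several for 180 and none for 30638. The single symbols belonged to 815 clones and 430 genes, of which 91 have a symbol other than a LOC number. Clones with several symbols or none were tested and counted but not named. Clones of one gene were tested separately.

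Within each loop the 4 log2 ratios were solved by least squares for the 4 lines, so that a gene-specific dye effect cancels. In leaf replicate 3 the 2 dye-swapped arrays of a pair were averaged. The resulting values per RNA sample were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with line as the factor of interest and replicate as a block. The replicate is a block by construction, since ratios exist only within a replicate. In leaf replicate 3 each dye-swapped pair was its own block. Tissues were fitted apart, with 5 residual degrees of freedom in leaf and 3 in root. Leaf estimates of 4x against 1x and of 2xR5 against 2xR3 drew on 3 replicates, and all root comparisons on 2 loops. The other leaf comparisons are measured within 2 loops (n = 2). Among these, replicate 3 also enters the estimates of the diploids against 1x and of 4x against the diploids, through its pair of 1x and 4x, so such an estimate can lie outside the values of both loops. The comparisons were 4x with 1x, the mean of the diploids with 1x, 4x with the mean of the diploids, the diploids with the mean of 1x and 4x, and 2xR5 with 2xR3, plus an F test for any difference. Benjamini-Hochberg adjusted p under 0.05 over the clones of a tissue was the threshold. A joint limma fit of both tissues tested whether an effect differed between them. No array held both tissues, so levels in leaf and root were not compared. A log2 ratio within an array is relative to the other clones, so the total amount of RNA per cell was not measured.

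The reproducible spread of a comparison was taken as the square root of the mean covariance over clones between replicates, with a 95% bootstrap interval over clones (1000 draws). Clones are not independent, and such intervals do not cover differences between plants.

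Genes to be named were fixed by rule before the data were examined. For 4x with 1x, and for the diploids with the mean of 1x and 4x, these were up to 10 rises and 10 falls of largest size among clones with 1 symbol, adjusted p under 0.05 and the same sign in every replicate. The other comparisons took 5 and 5. Where no clone passed, the 3 with the smallest p were named. From each gene list the 2 members with the smallest p in the first 2 of these comparisons were added. Other genes with a symbol other than a LOC number were chosen for naming after the results were seen, from those that passed, so they are examples. The 28 gene lists, cell type and stress markers included, were patterns for gene names. With symbols alone they matched PSBR (green tissue), PR1B (pathogen response) and IAA2 and IAA3 (auxin), so none reached the 5 genes set for a list test. In their place, 10 groups of symbols were written after the annotation was seen and before any value was. Symbols can be ambiguous: R1, placed in the defence and wound group, also names a starch-phosphorylating enzyme in potato. Groups with 5 or more measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over groups within a comparison, and again with an estimated correlation and with fry.

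The alternatives, except those named as added in the closing section, were chosen before the data were examined. They were an array-level fit without the replicate block, with and without a dye effect, median-centred and scaled arrays, clones with values on at least 75% of the arrays, 1 fit for both tissues, robust eBayes, clones averaged per gene, and leaving out each replicate. Scaling gave every array the same median absolute value. Other background correction, a filter on dim spots and slide as a block were not run, because they need spot intensities or slide records.

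The scripts were tested on simulated data with 200 changed clones. For 4x against 1x with 6001 simulated leaf clones, 38% of the clones changed 1.25-fold were recovered, 98% of those changed 1.5-fold, and all 50 of those changed 2-fold. With 8245 simulated root clones the shares were 4% at 1.25-fold, 68% at 1.5-fold and 90% at 2-fold. The data gave far more calls, 2386 in leaf and 2481 in root, so these shares need not hold there. Unchanged clones made up 6.15% of the simulated leaf calls and 7.75% of the root calls. The simulated test between tissues, on 5000 clones, recovered 95% of clones changed 2-fold in leaf alone, and unchanged clones made up 9.72% of its calls, above the 5% set. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.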

Results

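Potato plants carrying 1, 2 or 4 copies of the same monoploid genome were compared for transcript levels in growing leaflets and in growing root tips. The lines derive from one monoploid by chromosome doubling, so the series asks how expression changes with ploidy when the genotype stays the same. The 2 diploid lines, 2xR3 and 2xR5, give the difference between lines of equal ploidy. There were 12 leaf arrays, which held 3 RNA samples of each line, and 8 root arrays, which held 2 of each. Spots with a value numbered 12403 to 18629 per array and were fewest on the 4 arrays of leaf replicate 3. The number of arrays limits the precision: the median standard error of a log2 difference between 4x and 1x was 0.08 in both tissues. All signs assume that the deposited values are Cy5 over Cy3, which is likely but not stated.

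In leaf, most clones of the plasma membrane proton pumps, and transcripts of starch enzymes and of an ethylene receptor were higher in the tetraploid than in the monoploid, and those of a flavonoid enzyme were lower. One clone of GBSS, the granule-bound starch synthase, was higher by 0.85 ± 0.12 (log2, SE, n = 3; limma, Benjamini-Hochberg adjusted p = 9.62e-04), and another passed at 0.61. AMYA1, an alpha-amylase, rose by 0.61. PHA2, a plasma membrane H+-ATPase, rose in 3 of 4 clones, by 0.52 to 0.72, while the other clone stood at 0.14 and did not pass, and PHA1, another such pump, by 0.41. ERS, an ethylene receptor, rose by 0.68 ± 0.07 (limma, adjusted p = 1.80e-04), a 1.61-fold difference. Its single replicates gave 0.67, 0.72 and 0.65, and the naming rule required the same sign in each. F3H, flavanone 3-hydroxylase of the flavonoid pathway, fell by 0.97 ± 0.18 (limma, adjusted p = 0.003).

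Among the other genes with the largest rises were SRE1A (0.95), VPE2 (0.88), LOC102596783 (1.00), LOC102577928 (0.94), LOC102577499 (0.83), LOC102584141 (0.74) and LOC102577637 (0.73). The falls were led by LOC102604256 (-1.26), followed by LOC102577564 (-0.93), LOC102577839 (-0.90), LOC102593129 (-0.89), LOC102577624 (-0.74), LOC102577522 (-0.73), LOC102583085 (-0.72) and LOC102595604 (-0.67). FLS, flavonol synthase, gave opposite answers: one clone fell by 0.77 and another rose by 0.62, and their average stood at -0.079 and did not pass. CAT1, a catalase, did the same, with clones at 0.53 and -0.56. Of the 20 calls named by rule, 8 were lost without replicate 2 (LOC102577928, LOC102577499, LOC102577564, LOC102577624, LOC102577522, LOC102583085, LOC102595604 and FLS) and 2 without replicate 1 (LOC102577624 and LOC102583085). LOC102595604 stood at -0.41 without replicate 2. Of the 64 genes with several clones past the threshold, 6 had clones of opposite sign, LOC102577522 and LOC102595604 among them. The remaining symbols come without a description, so their function is left open here.

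By group, 3 of the 5 starch and sucrose clones rose and none fell. In membrane transport 4 of 6 clones rose, 3 of PHA2 and 1 of PHA1, while a PHA2 and a KST1 clone did not pass. Of 6 redox clones 1 rose and 3 fell, the falls being CAT1 at -0.56 and 2 clones of DHAR2 at -0.35 and -0.44. In the hormone and development group, ERS rose and CYCD3.3, a D-type cyclin, fell by 0.51, while the other 5 of 7 clones did not pass. The auxin genes IAA2 and IAA3, members of the Aux/IAA repressor family, stood at -0.05 each, and 0 of 2 clones passed over all clones or adjusted over the list alone. Leaving out 1 replicate moved IAA2 over -0.13 to 0.07 and IAA3 over -0.10 to -0.01. PSBR, a photosystem II subunit, stood at -0.26 (limma, adjusted p = 0.054), and both of its clones passed adjusted over the list alone. In amino acid metabolism 7 of 13 clones rose (camera, Benjamini-Hochberg adjusted p = 0.024). Of these, 6 are clones of METK1, an S-adenosylmethionine synthetase, and the call was lost with an estimated correlation, at an adjusted p = 0.712. The glycolysis and respiration group and the hormone group had a camera adjusted p = 0.476 each.

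Over all clones, 2386 of 6001 (39.8%) differed between tetraploid and monoploid leaves (limma, Benjamini-Hochberg), 1194 higher and 1192 lower in 4x. The changes were small: the median size among them was 0.35 on the log2 scale, and 24 clones changed at least 2-fold, 5 upwards and 19 downwards. Estimates of different replicates correlated at 0.612 to 0.784 across clones. The count was 194 without replicate 2 and 1239 without replicate 1, which leave a single closed loop, and 1252 of the 4335 clones with 2 full spots passed in both when each spot was tested alone.

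**Figure D1:**
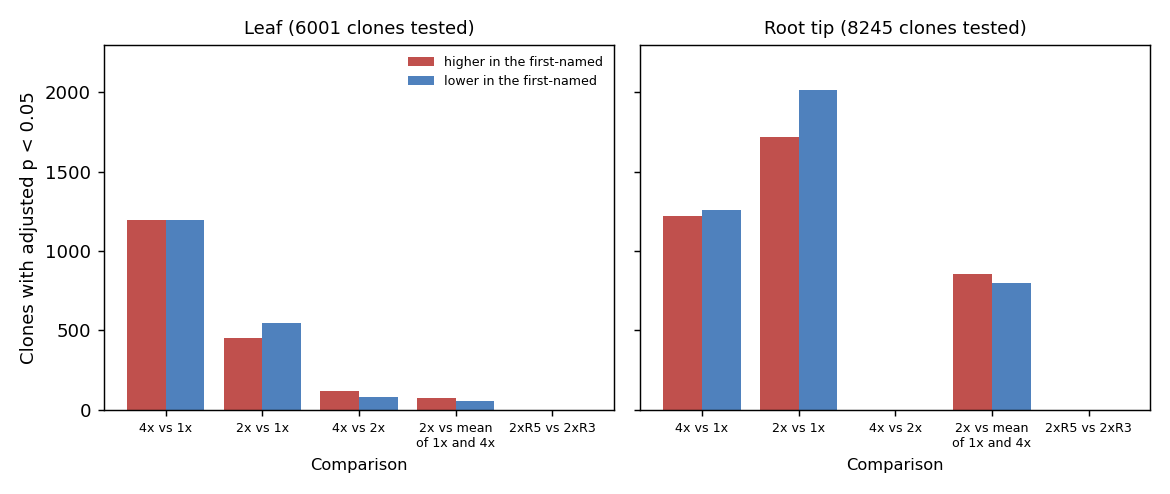
Number of clones with a Benjamini-Hochberg adjusted p under 0.05 (vertical axis) in each comparison (horizontal axis), in leaf and in root tip, with red bars for clones higher and blue bars for clones lower in the first-named line or lines. The tallest leaf bars belong to 4x against 1x (1194 and 1192 clones), the tallest root bars to the diploids against 1x (1721 and 2014), and the diploid lines show 0 clones against each other in both tissues.

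Between monoploid and diploid leaves, a cyclin was lower and most proton pump clones were higher in the diploids. CYCD3.3 showed the largest fall of a named gene, by 0.92 ± 0.09 (log2, SE, n = 2; limma, adjusted p = 5.00e-04), and PHA2 (0.37 to 0.48 in 3 of 4 clones), ERS (0.37), AMYA1 (0.52) and VPE2 (0.57) were higher in the diploids. The largest rises of named genes were in LOC102577499 (1.10), LOC102577567 (0.87), LOC102577835 (0.76), LOC102587499 (0.76) and LOC102577779 (0.69). The other large falls were LOC102581985 (-0.53), LOC102595604 (-0.53), LOC102599440 (-0.53) and LOC102577564 (-0.50). Another clone of LOC102595604 rose by 0.23, and CAT1 had clones at 0.57 and -0.34. In all, 994 clones (16.6%) passed in limma, 450 higher and 544 lower in the diploids. Of the 2386 clones that separated 4x from 1x, 816 also passed here with the same sign, but both comparisons use the same 1x samples, so shared calls arise without a shared change. The count was 22 without replicate 1 and 11 without replicate 2, since 1 loop then remains, and of the 10 calls named by rule 8 and 10 were lost there. The LOC102577567 call was lost with scaled arrays, with robust eBayes and with the 75% rule for missing values.

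The second doubling, from diploid to tetraploid leaves, had clones of flavonoid enzymes among its largest falls. F3H fell by 1.35 ± 0.18 and 1 FLS clone by 1.28 ± 0.15 (log2, SE, n = 2; limma, adjusted p = 0.005 for each), 2.55-fold and 2.43-fold. The other FLS clone stood at 0.22 and did not pass, and this group of 2 genes was too small for a group test. F3H stood at -0.90 without replicate 1 and did not pass. LOC102584296 stood at 0.43 without replicate 2 and did not pass either. PSBR fell by 0.38 in 1 of its 2 clones. PME1, a pectin methylesterase, rose by 0.62 and CYCD3.3 by 0.41. LOC102577928 (1.03), LOC102602308 (0.73), LOC102584296 (0.64) and SI1 (0.49) were the other large rises, and LOC102577835 (-1.20), LOC102604256 (-1.10) and LOC102598069 (-0.51) the other large falls. In all, 198 of 6001 clones passed, 117 higher and 81 lower in 4x. The number was 94 after scaling of the arrays, 494 in an array-level fit without the replicate block, 0 without replicate 1, 1 without replicate 2 and 520 without replicate 3. Of the 10 calls named by rule, 10 were lost without replicate 1 and 9 without replicate 2. Scaling ended the calls of LOC102602308, LOC102584296, SI1 and LOC102604256.

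In leaf the diploids differed from the mean of the end lines for few genes, which does not place them outside both. F3H (0.87 ± 0.16) and 1 FLS clone (0.89 ± 0.13) were higher in the diploids than in the mean of 1x and 4x (log2, SE, n = 2; limma, adjusted p = 0.021 and 0.011). F3H stood at 0.41 without replicate 1, where it did not pass, and at 1.32 without replicate 2. The other FLS clone stood at 0.09 and did not pass. STWRKY8, a WRKY transcription factor, was higher by 0.48 and CYCD3.3 lower by 0.67. The other rises were LOC102577835 (0.96), LOC102577499 (0.68), LOC102577779 (0.59), LOC102587499 (0.57), LOC102589596 (0.50), LOC102600029 (0.44) and LOC102577511 (0.36). LOC102577928 fell by 0.60. PSBR, IAA2 and IAA3 stood at 0.27, 0.23 and 0.19 and did not pass over all clones; both clones of each list passed adjusted over the list alone. The count was 130 (2.17%), 75 higher and 55 lower. After scaling of the arrays 45 passed and 34 of them were higher (75.6% against 57.7%). The calls of F3H, STWRKY8, LOC102577779, LOC102589596, LOC102600029 and LOC102577928 were lost there. Leaving out replicate 1 or replicate 2 left 1 clone each time, and 12 and 11 of the 12 calls named by rule were lost.

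Between pairs of ploidy levels in root tips, the clones that passed separated the monoploid from the other lines. ADH1, an alcohol dehydrogenase, was 26.1-fold lower in tetraploid than in monoploid root tips, at -4.70 ± 0.26 (log2, SE, n = 2; limma, adjusted p = 6.02e-04). XIP1-1-BETA, an X-intrinsic-protein aquaporin, was higher in 4x by 1.04 ± 0.25 (limma, adjusted p = 0.026), with 0.52 and 1.56 in the single replicates, but stood at 0.11 and did not pass after scaling of the arrays. Both auxin genes rose, IAA2 by 0.74 ± 0.13 and IAA3 by 0.59 ± 0.08 (limma, adjusted p = 0.011 and 0.006), and both passed adjusted over the list alone. After scaling they stood at 0.52 and 0.51 and did not pass. The largest rises of all named genes were LOC102577927 (3.69, 12.9-fold), LOC102577779 (2.59) and LOC102586657 (2.21).

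Further rises were LOC102577854 (1.29), LOC102598951 (1.28), LOC102577566 (1.11), LOC102601763 (1.09), LOC102606273 (1.05) and LOC102577514 (0.99). Further falls were LOC102584296 (-1.02), LOC102577712 (-0.99), LOC102577429 (-0.90), LOC102587499 (-0.90), LOC102577909 (-0.80), LOC102585483 (-0.79), LOC102581985 (-0.75), LOC102577790 (-0.70) and LOC102604560 (-0.68). The LOC102587499 value is of 1 clone, and another clone of it was higher in diploid than in 1x root tips, by 1.41. In the redox group 2 of 10 clones rose and 1 fell: NAD(P)H:QR, a quinone reductase, rose by 0.53, a DHAR2 clone rose by 0.26, and 1 clone of DHAR, dehydroascorbate reductase, fell by 0.58. The other DHAR clones stood at 0.29 and 0.12 and did not pass. SHKA, the first enzyme of the shikimate pathway, rose by 0.74 and SHMT, serine hydroxymethyltransferase, fell by 0.68, the 2 of 17 amino acid clones that passed. STWRKY8 rose by 0.34 and 0.37 in 2 clones. PSBR, measured as a green tissue marker in root tips, stood at 0.07 and did not pass. Of the starch and sucrose clones 0 of 8 passed. No group had a camera adjusted p under 0.651.

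In root 2481 of 8245 clones (30.1%) differed between 4x and 1x (limma, Benjamini-Hochberg), 1223 higher and 1258 lower in 4x. At 2-fold or more the split was uneven, with 185 higher and 28 lower. The estimates of both loops correlated at 0.806 across clones. With arrays scaled to a common spread the count was 173 (107 higher, 61.9%). Scaling also ended the calls of LOC102577779, LOC102598951, LOC102577566, LOC102606273, LOC102577514, LOC102577712, LOC102577429, LOC102587499, LOC102577909, LOC102581985 and LOC102577790. LOC102577429 stood at -0.54 without replicate 5, where the LOC102604560 call was lost, and LOC102577909 had -1.26 and -0.34 in the single replicates. The count was 716 without replicate 4 and 646 without replicate 5, over the 5121 clones of both tissues, where 1 loop is left and leaf supplies the spread.

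**Figure D2:**
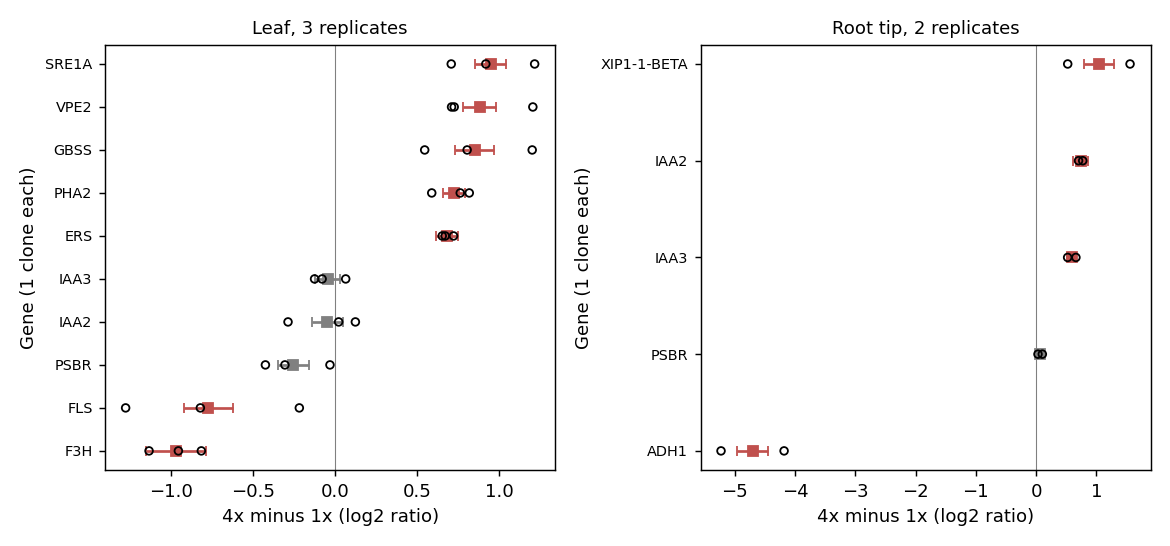
Difference between 4x and 1x on the log2 scale (horizontal axis) for the genes named by the rule set beforehand that have a symbol other than a LOC number, 1 clone each (vertical axis), in leaf and in root tip. Squares with bars are the limma estimate and its standard error, red where the adjusted p is under 0.05 and grey otherwise, and open circles are single replicates; ADH1 lies at -4.70 in root, and F3H at -0.97 in leaf.

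Between monoploid and diploid root tips, XIP1-1-BETA was higher and ADH1 lower in the diploids. LOC102577927 rose by 3.82 ± 0.26 (14.1-fold), LOC102577779 by 2.82, LOC102586657 by 2.54, XIP1-1-BETA by 1.74 and LOC102598951 by 1.72 (log2, SE for the first, n = 2). ADH1 fell by 2.27 ± 0.23 (limma, adjusted p = 0.002), and the falls of LOC102577909 (-0.85, with -1.23 and -0.47 in the single replicates), LOC102581985 (-0.80), SHMT (-0.71) and LOC102577790 (-0.70) followed. IAA2 and IAA3 rose by 0.73 and 0.50. MIP2 (0.94), SHKA (0.86), NAD(P)H:QR (0.63), CDPK1, a calcium-dependent protein kinase (0.50), GRX2 (0.37) and the D-type cyclins CYCD3.3 (0.38) and CYCD3.2 (0.30) were higher in the diploids as well. Lower in the diploids were 1 clone each of GBSS (-0.37), BEL5, a BEL1-like homeodomain protein (-0.29), GAPDH, of glycolysis (-0.25), and KST1, a potassium channel (-0.26). Other clones of GBSS (-0.24), GAPDH (-0.11 to 0.04) and KST1 (-0.08) did not pass.

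By group, 4 of 9 defence and wound clones rose in the diploids and 1 fell: 2 clones of STWRKY8 (0.55 and 0.59), PPO, a polyphenol oxidase (0.35), and POTLX-3, a lipoxygenase (0.33), rose, and R1, an ambiguous symbol, fell by 0.34. In the hormone and development group 4 of 9 clones rose and 1 fell. Amino acid clones split, 4 up and 4 down of 17. The camera adjusted p of these 3 groups was 0.342 each. Over all clones 3735 (45.3%) passed in limma, 1721 higher and 2014 lower in the diploids, and of those at 2-fold or more 222 were higher and 16 lower. With scaled arrays 683 passed, 457 of them higher (66.9% against 46.1%), and the calls of SHMT, LOC102598951 and LOC102577909 were lost there. Over the 5121 clones of both tissues the count was 970 without replicate 4 and 1424 without replicate 5.

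Between diploid and tetraploid root tips no clone passed in limma with Benjamini-Hochberg adjustment, and 582 of 8245 had an unadjusted p under 0.05. The named genes with the smallest p were ADH1 at -2.43 ± 0.23 (limma, adjusted p = 0.113; -2.41 and -2.45 in the replicates), LOC102577712 at -0.93 and LOC102587499 at -0.69 (limma, adjusted p = 0.349 for each). After scaling of the arrays 13 clones passed, ADH1 among them with a larger fall. In an array-level fit without the replicate block 5 clones passed, ADH1 among them, and in 1 fit of both tissues 17 did. The amino acid group was lower in 4x (camera adjusted p = 0.007), with 0 of 17 clones past the threshold. Of the 17, 9 are clones of METK1, at -0.22 to -0.16, and the others ranged from -0.186 to 0.065. The call was lost with an estimated correlation, at a camera adjusted p = 0.906.

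Root diploids differed from the mean of the end lines for many genes, as a diploid level near that of 4x also would. LOC102577927 (1.97), LOC102577779 (1.53), LOC102586657 (1.44), XIP1-1-BETA (1.22), LOC102587499 (1.21), LOC102605260 (1.19), LOC102598951 (1.08), LOC102577514 (0.88), LOC102586069 (0.61) and LOC102606273 (0.58) were higher in the diploids than in the mean of 1x and 4x. The falls were smaller, from LOC102583085 (-0.44), LOC102581985 (-0.43), SHMT (-0.37), LOC102577790 (-0.35), LOC102587142 (-0.32) and LOC102595604 (-0.30) to RGGA (-0.29), LOC102598711 (-0.26), LOC102577515 (-0.25) and LOC102577454 (-0.25). IAA2 (0.36) and IAA3 (0.20) passed over all clones and adjusted over the list alone, but not after scaling or with the 75% rule for missing values. Clones of LOC102587499 went both ways in root tips. Without replicate 5 LOC102577779 stood at 0.97 and LOC102587499 at 0.73, and without replicate 4 LOC102577454 stood at -0.15. SHMT had -0.54 and -0.20 in the single replicates. Of the 17 calls named by rule and measured in both tissues, 9 were lost without replicate 4 and 7 without replicate 5, IAA3 both times and IAA2 without replicate 4. PSBR stood at -0.17, with -0.27 and -0.07 in the single replicates, and did not pass. The count was 1655 (20.1%), 857 higher and 798 lower, with 77 higher and 4 lower at 2-fold or more (limma). It was 167 with scaled arrays, of which 140 were higher (83.8% against 51.8%), 3655 without the replicate block, and over the 5121 clones of both tissues 325 without replicate 4 and 524 without replicate 5. Of the rises and falls named first, scaling kept the calls of LOC102586657, LOC102577514, LOC102586069 and LOC102583085.

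On the span from 1x to 4x the diploids stood at different places in the tissues. In leaf they lay 55.1% of the way (95% bootstrap interval 53.1 to 56.9), and in root 105% (103 to 108), computed from covariances between different replicates so that the shared monoploid adds no bias. Among leaf clones that separated 4x from 1x, the diploid mean lay between the end lines for 1948 of 2386 (81.6%). Among the root clones it lay beyond 4x for 1376 of 2481 (55.5%) and between for 1102. These counts use the same 1x samples on both sides, which the covariances avoid.

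**Figure D3:**
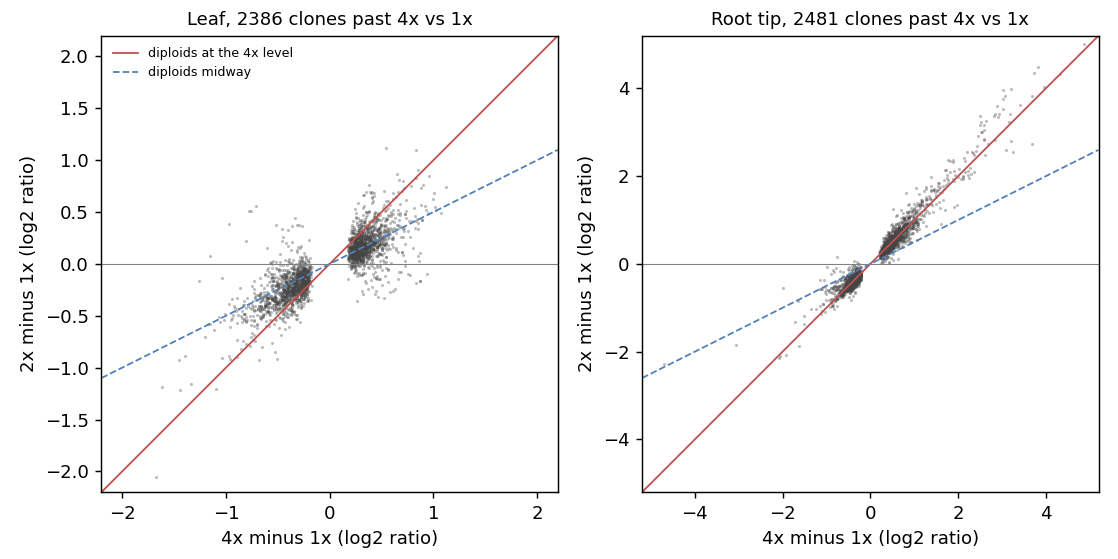
Each point is a clone that passed 4x against 1x, with its difference 4x minus 1x (horizontal axis) and diploid mean minus 1x (vertical axis), both log2 ratios, in leaf and in root tip. Leaf points gather near the dashed line of diploids midway (median position 57.5%), root points near the red line of diploids at the 4x level (median position 103%). Both axes use the same 1x samples.

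No clone separated the 2 diploid lines in either tissue when each was fitted alone on all replicates. In leaf 0 of 6001 clones passed in limma with Benjamini-Hochberg adjustment and 518 had an unadjusted p under 0.05, and in root 0 of 8245 passed and 301 had one. In leaf 4 clones passed without replicate 3. In root 11 passed with both tissues in 1 fit, 2 without replicate 4 and 1 without replicate 5, and 2 in an array-level fit without a dye effect or the replicate block. The named leaf genes with the smallest p were LOC102586069 (0.43, adjusted p = 0.285 in limma), LOC102577716 (0.58) and LOC102596122 (0.30), and in root METK1 (-0.47), CYCD3.3 (0.42) and LOC102577613 (-0.33), each with a limma adjusted p = 0.998. CYCD3.3 had 0.57 and 0.27 in the single root replicates. The reproducible spread between the diploid lines (SD over clones) was 0.08 in leaf (0.07 to 0.08) and 0 in root (0 to 0.04), against 0.27 for 4x with 1x in leaf and 0.43 for the diploids with 1x in root. In root the amino acid group was lower in 2xR5 (camera adjusted p = 5.78e-06). Its 17 clones gave 9 past the threshold adjusted over the group alone. All 9 are clones of METK1, which may report 1 transcript. The call was lost with an estimated correlation, at a camera adjusted p = 0.583. Any difference among the 4 lines was found for 1779 leaf clones (29.6%) and 2080 root clones (25.2%) by limma's F test. With scaled arrays these numbers were 1587 and 71, and without replicate 2 the leaf number was 4.

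Some genes changed differently in leaf and root. ADH1 rose by 0.34 in tetraploid leaves and fell in tetraploid root tips. CYCD3.3 was lower in diploid leaves by 0.92 and higher in diploid root tips by 0.38, a difference between tissues of -1.30 (joint limma fit, adjusted p = 1.46e-05). Across the 5121 clones measured in both tissues, differences between 4x and 1x correlated at r = 0.117 (0.084 to 0.148; Spearman 0.163), those between diploids and 1x at 0.352, and those of the diploids from the mean of 1x and 4x at 0.380. Those between 4x and diploids gave r = 0.010, and those between the diploid lines -0.093. These are correlations over clones, which are not independent replicates. For 4x against 1x, 192 clones rose in both tissues where independent lists would share 126, and 251 fell in both where they would share 166. For the diploids against 1x, 187 rose in both against 68.2 and 221 fell in both against 121. Opposite calls were fewer than independent lists would give, 185 against 292 for 4x against 1x and 49 against 182 for the diploids against 1x.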

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

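The tests of explanations in this part were chosen after the results they bear on had been seen, except for the assignments of the leaf RNA samples. What brought up the results here is a difference between leaf and root under the same comparison, tested in the joint limma fit with Benjamini-Hochberg adjustment. No array group held 4 or more arrays, so single outlying arrays were not tested.

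The effect differed between the tissues in 1614 of 5121 clones for 4x against 1x, in 1221 for the diploids against 1x, in 74 for 4x against the diploids and in 189 for the diploids against the mean of 1x and 4x. For 2xR5 against 2xR3 it did so in 0 clones, with 375 at an unadjusted p under 0.05. In the same order the first 4 counts were 928, 240, 200 and 85 with scaled arrays. Leaving out 1 replicate moved them to 694 to 1658, 421 to 1232, 0 to 115 and 39 to 168, with the lowest without replicate 5, 4, 2 and 2. Values below are the leaf difference minus the root difference on the log2 scale.

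For 4x against 1x the largest was ADH1, the alcohol dehydrogenase, at 5.05. GBSS stood at 1.17, ERS at 0.76, SRE1A at 0.67 and PHA2 at 0.47, so for each the leaf difference lay above the root difference. The auxin genes IAA2 (-0.79) and IAA3 (-0.64) lay on the root side. Of the LOC genes named for leaf, LOC102596783 stood at 1.02, LOC102593129 at -0.96, LOC102577624 at -0.92 and LOC102577522 at -0.77. Of those named for root, LOC102577927 stood at -3.54, LOC102577779 at -2.44, LOC102586657 at -2.33, LOC102606273 at -1.57, LOC102577566 at -1.16, LOC102584296 at 1.48, LOC102577429 at 1.39, LOC102577712 at 1.21, LOC102577790 at 0.91, LOC102587499 at 0.73 and LOC102581985 at 0.43.

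For the diploids against 1x, CYCD3.3 stood at -1.30, ADH1 at 2.45, LOC102577927 at -3.23, LOC102586657 at -2.66, LOC102577499 at 0.71, LOC102599440 at -0.74 and LOC102577790 at 0.67, and 2 clones of LOC102577779 at -1.84 and -2.29. For 4x against the diploids, ADH1 stood at 2.59, LOC102577712 at 1.11 and LOC102602308 at 1.03. For the diploids against the mean of 1x and 4x, CYCD3.3 stood at -0.99, LOC102605260 at -1.59, LOC102586657 at -1.50, LOC102577927 at -1.46, LOC102586069 at -0.40 and LOC102577790 at 0.35.

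Monoploid root tips stood apart from the other 3 lines, with 3735 clones against the diploids and 0 between diploids and 4x. The 0 counts clones past the threshold and does not show that diploids and 4x were alike. Their difference had a reproducible SD of 0.085 (0.072 to 0.098; r = 0.245 between the loops), against 0.434 for the diploids with 1x. A single aberrant monoploid sample is argued against by the correlation of 0.854 between the loops, if these hold separate monoploid RNA: the labels call them biological replicates but do not say that the plants were separate. Stretching of the arrays with monoploid RNA is argued against by the spots. It would widen the differences between the 2 spots of a clone as much as the clone values, whose SD was 2.58 and 2.31 times that of the other arrays in the loops, but the SD of spot differences was 0.923 and 1.06 times that of the others (6801 clones). That any 2 lines differ this much whatever their ploidy is argued against by the 2 diploid lines, whose reproducible SD has an upper bound of 0.035. They are 1 pair, and the interval is over clones, so it does not bound how far other lines of equal ploidy differ. Ploidy itself and some other property of the monoploid line cannot be told apart, because the design holds 1 monoploid line.

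Leaf and root differences between 4x and 1x had little in common (r = 0.117). Noise does not account for it: corrected for the spread between replicates, the correlation was 0.134 (0.098 to 0.171). Tissue, the age of the plants and the amplification of the root RNA cannot be told apart: the tissues were sampled at 0 shared plant ages, and neither is described as having both amplified and unamplified RNA. A tissue difference stays open as untested.

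Other assignments of the lines to the leaf RNA samples within each block were counted, 100 of them including the real one unless stated. The bound was set beforehand: chance counts as excluded when under 5% of the assignments, the real one included, give as many clones. It concerns the assignment of these RNA samples only. No label ties them to separate plants, so chance differences between plants are not covered. For any difference, 1 assignment, the real one, reached 1779 clones, and the highest other gave 1498, so by that bound chance in the assignment is excluded. The same holds for 4x against 1x, with 1 assignment, 2386 real clones and 1679 in the highest other. For the diploids against 1x, 3 assignments reached the real 994, which is under the bound, although the highest other gave 2041. For 4x against the diploids, 8 reached the real 198 and the highest gave 2079, and chance cannot be excluded. For the diploids against the mean of 1x and 4x, 3 of the 36 distinct assignments reached the real 130, the highest gave 1187, and chance cannot be excluded. For the diploid lines all 100 reached the real 0, and the highest other gave 64. Seen afterwards, the highest other assignment of each comparison kept all 3 monoploid or all 3 tetraploid samples together as 1 line, so these are not assignments without ploidy in them.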

How the results depend on the processing

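Alternatives added after seeing the data were the tests of single spots, clones with both spots on every array, leaf without its most widely spread array, the single comparisons without a dye effect, and the leave-one-out counts of the tissue difference. Robust eBayes, clones averaged per gene, clones with values on 75% of the arrays and clones with both spots on every array kept every count within 1.5 times. Turning every sign swaps higher and lower by construction. Background correction, a filter on dim spots and slide as a block were not run. Signal over background is not known here.

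The array-level fit with no replicate block gave 494 leaf clones for 4x against the diploids, 518 for the diploids against the mean of 1x and 4x, and in root 3303 for any difference, 3655 for the diploids against the mean and 5 for 4x against the diploids; it treats the 2 arrays of each RNA as independent, and it moved no other count by over 1.5 times. Without a dye effect, and with no replicate block, these were 343, 384, 3828, 4006 and 57, and 2 clones for the root diploid lines. Scaled arrays gave 94 and 45 in leaf for the first 2 of these, and in root 71 for any difference, 173 for 4x against 1x, 683 for the diploids against 1x, 13 for 4x against the diploids and 167 for the diploids against the mean. For the tissue difference scaling gave 928 (4x against 1x), 240 (diploids against 1x), 200 (4x against diploids) and 85 (diploids against the mean), and for the leaf-root correlation 0.075 (4x against 1x), 0.341 (diploids against the mean) and -0.047 (diploid lines). Root arrays with monoploid RNA had SDs of 0.544 to 0.609 and the others 0.213 to 0.249. Scaling evens out the median absolute value of the arrays, which need not make these SDs equal. Over clones past the F test the correlation was 0.399 (diploids against 1x) and 0.446 (diploids against the mean). With both tissues in 1 fit, on fewer clones, root gave 2408 for the diploids against 1x, 17 for 4x against the diploids and 11 for the diploid lines. In root the 2 spots of a clone argue against stretching of the arrays with monoploid RNA. The SD of spot differences on those arrays was 0.923 and 1.06 times that on the others, against 2.58 and 2.31 for clone values. Scaling root arrays to a common spread therefore also shrinks differences between lines. How many of the lost root calls this accounts for was not tested. For the root zeros and the scaled leaf counts the cause was not tested.

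Clones whose 2 spots both passed alone numbered in leaf 854 (any), 1252 (4x against 1x), 430 (diploids against 1x), 101 (4x against diploids) and 44 (diploids against the mean), and in root 1255, 1500, 2481 and 915 (any, 4x against 1x, diploids against 1x, diploids against the mean); 4335 leaf and 6801 root clones have both. Without the array of 2xR3 and 4x in replicate 1 the leaf counts in that order were 237, 1183, 75, 0 and 1, where the opened loop no longer cancels the dye effect by construction; the cause of the lower counts was not tested. The array-level fit without that array, with no replicate block, kept all but the diploids against the mean (293) within 1.5 times.

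Leaving out 1 replicate gave leaf ranges of 4 to 1514 (any), 194 to 2159 (4x against 1x), 11 to 988 (diploids against 1x), 0 to 520 (4x against diploids), 1 to 163 (diploids against the mean) and 0 to 4 (diploid lines). The low ends come without replicate 1 or 2, when 1 loop is left. Root ranges were 673 to 739, 646 to 716, 970 to 1424, 15 to 50, 325 to 524 and 1 to 2 in the same order, on the clones of both tissues. The tissue difference ranged over 694 to 1658 (4x against 1x), 421 to 1232 (diploids against 1x), 0 to 115 (4x against diploids), 39 to 168 (diploids against the mean) and 0 to 2 (diploid lines).

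Of 106 calls of named genes, scaling kept 60 and lost 46, and of 17 values without a call it gained 1 (ADH1 in root, 4x against the diploids), averaging per gene lost 14 calls, and robust eBayes lost 1. Of 52 leaf calls, 32 were lost without replicate 1, 38 without replicate 2, 1 without replicate 3 and 30 without the array of 2xR3 and 4x; of 38 root calls on clones of both tissues, 9 were lost without replicate 4 and 8 without replicate 5. Reversals touched values that had not passed: IAA2 in leaf, 4x against 1x, ranged from -0.13 to 0.072 over the left-out replicates and stood at 0.022 in the array-level fit without the array of 2xR3 and 4x, and PSBR in root stood at -0.013 when averaged per gene. The group calls for amino acid metabolism were lost with an estimated correlation in all 3 comparisons that had one, and scaling added group calls for the root diploid lines in starch and sucrose (adjusted p = 0.013) and redox (0.044).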

Other observations

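All tests in this part were chosen after the results were seen. The absence of LDH-2 and PK among the genes past the threshold in root had been seen.

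METK1, the S-adenosylmethionine synthetase, was measured by 9 clones in root and 8 in leaf. In leaf all 8 clones were higher in 4x than in 1x, by 0.11 to 0.37, and 6 of them rose in limma. In root all 9 were lower in 2xR5 than in 2xR3, by -0.51 to -0.44, although 0 passed over all clones and the unadjusted limma p ranged from 0.003 to 0.011. The median over the clones was -0.35 in replicate 4 and -0.58 in replicate 5; METK1 was named for its small p, so this is no separate test. Several clones may report 1 transcript and so 1 measurement, which is consistent with the loss of the group call at an adjusted p of 0.583 with an estimated correlation. No biological explanation was tested, because the labels give no difference between the diploid lines beyond their names.

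ADH1 was graded over the root lines. Relative to the loop mean its log2 level was 2.31 ± 0.54 in 1x, 0.47 ± 0.19 in 2xR5, -0.39 ± 0.16 in 2xR3 and -2.39 ± 0.20 in 4x (SD, n = 2). In leaf it went the other way, at 0.34 for 4x against 1x. As a hypothesis, root tips of lower ploidy may have had less oxygen, under which alcohol dehydrogenase is induced in plant roots. LDH-2, a lactate dehydrogenase, and PK, a pyruvate kinase, would then be lower in 4x too. Their 1 clone each stood at -0.09 and -0.22, a median of -0.157, and neither passed (limma, adjusted p = 0.383 and 0.138). That lies between the bounds set for and against, so the hypothesis stays open.

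The dye effect differed between parts of the leaf data. It was shared by leaf replicates 1 and 2 (r = 0.852 across clones, SD 0.182 and 0.167), was smaller in replicate 3 (SD 0.087), with r = -0.191 and -0.268 to the others, and was smallest in the root loops (SD 0.046 and 0.053).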
